A study of Populus tremula x Populus alba with 20 samples.

How the data were processed

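The data were 20 one-colour (Cy3) Agilent arrays of poplar leaf RNA (total RNA by a CTAB protocol, young source leaves at leaf plastochron index 5), on a design whose probes are placed on the Poptr 1.0 build of the Populus trichocarpa genome, while the plants were hybrids of Populus tremula and Populus alba. Groups followed the labels: genotypes WT, F10 and F52 (plastidic Irp9), I6 (cytosolic Irp9) and N31 (NahG), each at normal (27/17 °C) and high (35/25 °C) temperature for 1 week, 2 biological replicates per group.

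Per the file headers, the deposited scanner files hold spot intensity values: mean spot signal, median local background and a processed signal that the authors made with Agilent Feature Extraction by background subtraction and detrending within each array, with surrogate values for signals not above background and no scaling between arrays. The file headers give version 10.5.1.1 of Feature Extraction and the submitters' processing notes give 9.1. The deposited series value table holds log2 values that the authors scaled by subtracting each array's 75th percentile, which was checked against the scanner files: 18 of the 20 columns matched their own file (r of at least 1.00 when rounded, highest median absolute difference 0.0235), and the 2 columns of WT at high temperature were exchanged relative to their files. Both files belong to the same group, so group means do not depend on this exchange. Results that name 1 replicate of that group follow the scanner files. Column medians of that table ranged from -3.74 to -3.21. The processed signal of the scanner files was used for the main values and the series value table as an alternative.

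Control spots and spots marked as outliers were left out, spots of the same probe were averaged, and log2 processed signal minus the 75th percentile of non-control spots of that array gave the normalized signal. Of 61657 non-control spots and 56623 probes, the 34650 probes that were well above background on both arrays of at least 1 group were tested, which covered 32553 genes or transcripts; 26932 of the tested probes had an informative description, and 71.5% of all probes did. The 75th percentile of the processed signal ranged from 238 to 828. Precision is limited by the number of arrays, 2 per group.

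Means of the 10 groups were fitted over all 20 arrays with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table), contrasts were tested with empirical Bayes moderated statistics at default settings (two-sided), and p was adjusted by Benjamini and Hochberg over the probes tested within each of 21 comparisons. A probe was called at an adjusted p under 0.05. The comparisons were the effect of temperature averaged over genotypes and in each genotype, the 3 Irp9 lines against WT, plastidic against cytosolic Irp9 and the NahG line against WT, each averaged over both temperatures, each line against WT at each temperature, and the difference of the temperature effect between each line and WT. Comparisons of lines share the WT arrays, so the overlap of F10 and F52 was set against 100 simulations of unchanged groups that share them.

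Before the data were examined, 28 gene lists were fixed as search patterns on gene names and descriptions, 4 of them markers of other cell types (xylem and secondary wall, phloem and storage, dividing cells, epidermis and cuticle), along with the groups, tests, filter, alternatives and the rule for named genes. A gene was represented by its tested probe with the highest mean, and lists under 5 genes were not tested. Patterns match words of a description, so the xylem and secondary wall list holds any cellulose synthase, laccase, fasciclin or COBRA gene. Of 5060 genes in any list, 115 were in several. Lists were tested with camera at a preset correlation of 0.01, which compares a list with the other genes, and again with an estimated correlation, and p was adjusted over the 28 lists. Fry, which asks whether a list's genes move, on balance, 1 way, called 9 lists for the averaged temperature effect, 6 for the Irp9 lines, 11 for plastidic against cytosolic Irp9 and 1 for the NahG line. With an estimated correlation camera called 0 lists for the Irp9 lines, plastidic against cytosolic Irp9 and the NahG line, with 3, 5 and 1 at an unadjusted p under 0.05.

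Genes named for the size of their change passed the threshold, had an informative description, were well above background on all arrays of at least 1 group compared, and had arrays that did not overlap between the 2 sides within each temperature or genotype averaged over. The rule took the 10 largest rises and falls for the averaged temperature effect and the Irp9 lines and the 5 largest for every other comparison. The 3 members of each list with the smallest adjusted p were named in addition, whether or not they met these conditions. A gene name is given as in the files, and the meaning of the suffix (C) in some of them is not stated there.

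The alternatives were normexp background correction with an offset of 50 on mean and background signal, quantile normalization, median centring over the probes tested, no filter on dim probes, only probes well above background on all 20 arrays, empirical Bayes with trend and robust settings, replicate, slide or scan as a block, the values of the series value table, only the arrays of the groups compared, and leaving out each array in turn. Fits without the arrays of slides 3 to 5, without F10 and within single slides were added after the data were seen. Slides 3 to 5 held all arrays of F10. Without them, and within slides 1 and 2, the Irp9 lines were F52 and I6, and plastidic Irp9 was F52 alone. The temperature effect without them was averaged over the other genotypes. The averaged comparisons were also set against other splits of the arrays, 100 drawn with a fixed seed or all 35 for the NahG line. Recovery was tested on simulated data in which 200 probes were changed, 50 at each size: for the averaged temperature effect 70, 94, 100 and 100% were called at log2 changes of 1, 2, 3 and 4, and for F10 against WT at normal temperature 6, 60, 76 and 82%, with 10 and 4 unchanged probes called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Groups of 2 arrays are too small for a test of single outlying arrays, and none was made.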

Results

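Transcript levels were measured in young source leaves of hybrid poplar (Populus tremula x Populus alba) on 20 one-colour arrays. Wild-type plants (WT) were compared with 4 transgenic lines. Lines F10 and F52 carried Irp9, a bacterial salicylate synthase that makes salicylic acid from chorismate, directed to the plastid. Line I6 carried Irp9 in the cytosol, and line N31 carried NahG, a bacterial enzyme that breaks salicylic acid down to catechol. Plants of each genotype stood for 1 week at a normal (27/17 °C, day/night) or a high (35/25 °C) temperature, which gave 10 groups of 2 biological replicates. The 75th percentile of the processed signal ranged from 238 to 828 over the 20 arrays, and 52.3 to 64.8% of spots lay well above background. Arrays of a group correlated with r of 0.943 to 0.982, computed across probes, which are not independent replicates. The number of arrays limits the precision of each value. The arrays were scanned on 5 slides in 3 scans, and the 4 arrays of F10 all belonged to the third scan. A probe was called when its adjusted p (limma, Benjamini-Hochberg over 34650 probes) lay under 0.05. Changes are given as log2 differences ± standard error (SE), and positions are those of the probe on the Poptr 1.0 build. Where a gene was not well above background on at least 50% of the arrays of the lower group, its fold is a lower bound, written as "at least" and computed after signals under an array's lowest well-above-background signal were raised to that signal. A log2 difference beside such a fold is the one fitted and is less certain.

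The transgenes were measured first, because the series asks how altered salicylic acid changes the response of poplar to heat. Irp9 had a mean normalized signal of 2.01 ± 0.55 (SD, n = 4) in F10, 1.27 ± 0.41 (SD, n = 4) in F52 and 0.60 ± 0.77 (SD, n = 4) in I6. In the control background its probe read -6.98 ± 0.60 (SD, n = 4) in WT and -6.35 ± 0.35 (SD, n = 4) in N31, on log2 scale relative to the 75th percentile, and none of these 8 arrays was well above background. Irp9 was higher in the plastidic lines than in I6 by 1.04 ± 0.30 (8 arrays against 4, adjusted p = 0.0445). NahG read 3.41 ± 1.38 (SD, n = 4) in N31 and -6.22 ± 1.35 (SD, n = 4) in WT, where 1 of 4 arrays was well above background. NPTII, a kanamycin resistance marker, was high in N31 alone, at 4.07 ± 0.50 (SD, n = 4). HPTII, a hygromycin resistance marker, and the green fluorescent protein markers mGFP5 and rsGFP were high in the 3 Irp9 lines, where HPTII had means of 8.03 in F10, 7.45 in F52 and 6.61 in I6. These 3 markers also read above the level of WT at normal temperature on both WT arrays at high temperature, both N31 arrays at high temperature and replicate 1 of N31 at normal temperature. Their level on those arrays was 0.148 to 0.504% of that in the Irp9 lines.

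**Figure D1:**
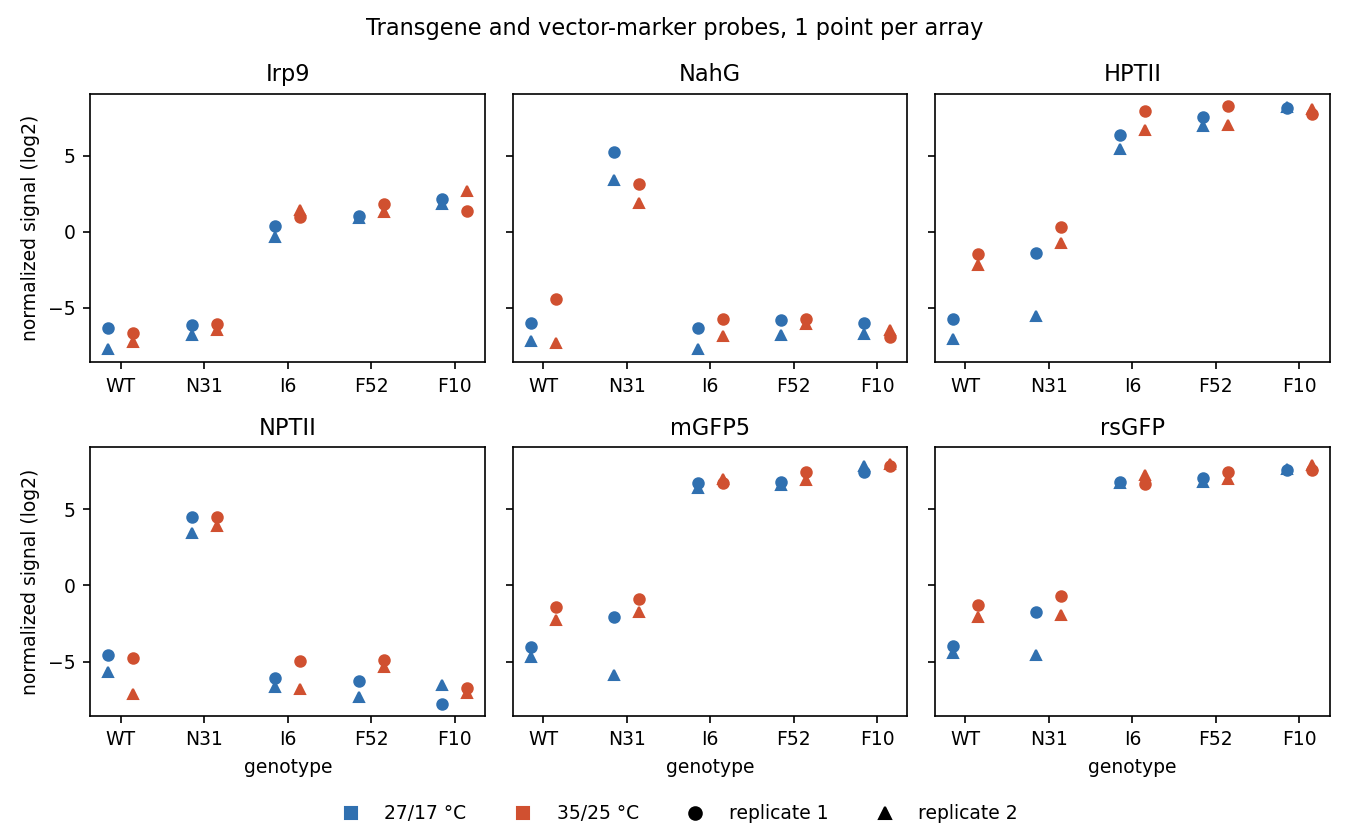
Normalized log2 signal (vertical axis) of 6 transgene and vector-marker probes by genotype (horizontal axis), 1 point per array, with colour for temperature and symbol for replicate. Irp9 had genotype means of 0.60 to 2.01 in I6, F52 and F10 against -6.98 in WT, and NahG had a mean of 3.41 in N31 against -6.22 in WT.

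Heat shock proteins were among the largest rises at high temperature averaged over the 5 genotypes (10 arrays against 10). A chloroplastic small heat shock protein, POPTR_0012s02930 (chromosome 12, 2372330 to 2372389), rose at least 361-fold, by 8.73 ± 0.56 on log2 scale (adjusted p = 1.24e-06). Small heat shock proteins bind unfolding proteins and keep them from clumping. The 18.2 kDa class I heat shock protein POPTR_0010s20300 (chromosome 10, 17942479 to 17942538) rose 62.2-fold (5.96 ± 0.28), and the 22.7 kDa class IV protein POPTR_0013s09600 rose at least 90.6-fold. Heat shock protein 83, EST_CV239446(C), a chaperone of signalling proteins, rose 35.6-fold (5.15 ± 0.21, adjusted p = 4.25e-08), and luminal-binding protein 5, POPTR_0013s01870, a chaperone of the endoplasmic reticulum, rose at least 24.9-fold (5.19 ± 0.22; well above background on 1 of 10 arrays at normal temperature). Bark storage protein B, POPTR_0019s07690, a nitrogen store, rose 31.6-fold (4.98 ± 0.61). An EG45-like protein, POPTR_0018s10730, fell by 4.05 ± 0.30 (adjusted p = 4.81e-06), and a glucan endo-1,3-beta-glucosidase, POPTR_0001s22860, one of the pathogenesis-related enzymes, fell by 3.52 ± 0.22 (adjusted p = 9.71e-07). The chloroplastic ferritins POPTR_0006s10480 and EST_CV263749, which store iron, changed by -3.64 ± 0.60 and -2.84 ± 0.50 (the second at least 4.42-fold). A gene described as HEADING DATE 3A, POPTR_0020s00550, the name of a flowering signal of rice, fell at least 4.25-fold.

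**Figure D2:**
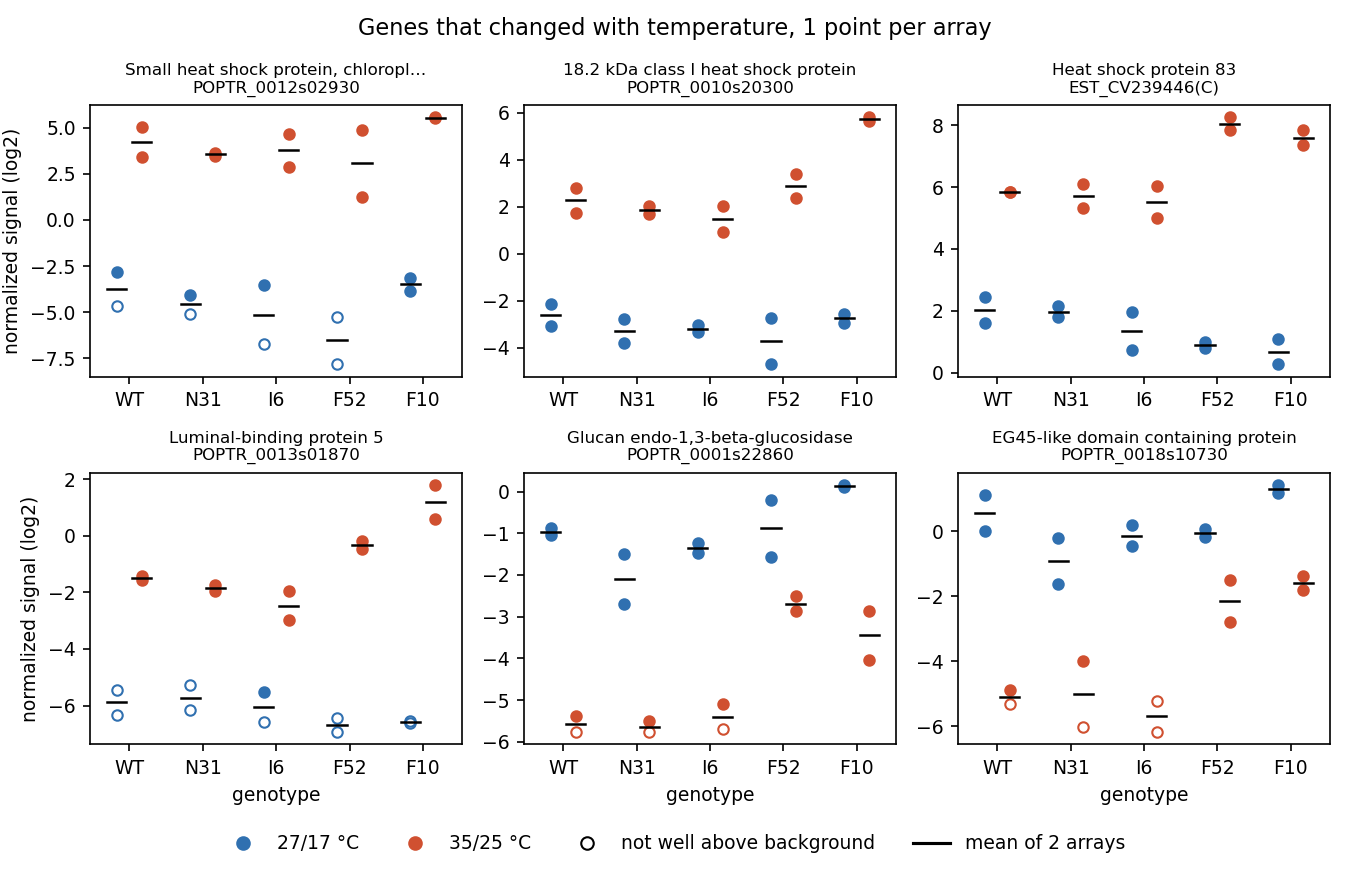
Normalized log2 signal (vertical axes) of 6 genes named for the temperature effect, by genotype (horizontal axes), 1 point per array and a line for the mean of 2 arrays, with open points not well above background. Heat shock protein 83 had group means of 0.68 to 2.04 at normal and 5.52 to 8.04 at high temperature, and the glucan endo-1,3-beta-glucosidase had means of -2.10 to 0.13 and -5.64 to -2.69.

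Of 54 small heat shock protein genes measured, 33 rose, 4 fell and 17 did not pass, with 34 and 7 when adjusted over the list alone. The list had a median of 1.60 and was called against the other genes (camera adjusted p = 4.97e-20, and adjusted p = 0.0452 with an estimated correlation). Among 254 large heat shock proteins and chaperones, 61 rose and 7 fell, with 62 and 10 adjusted over the list alone, and the list was called upward (adjusted p = 6.81e-06, and adjusted p = 0.0146 with an estimated correlation). A second gene for heat shock protein 83, POPTR_0017s01160, rose by 4.24 ± 0.23. Of 31 heat shock transcription factors 9 rose and 1 fell (10 and 2 adjusted over the list alone), among them HSF30, POPTR_0006s24330, at 1.40 ± 0.18. That list was called upward (adjusted p = 0.0198), though not with an estimated correlation (adjusted p = 0.169 with an estimated correlation). Glutathione S-transferases, which join glutathione to toxic compounds, rose in 19 of 70 genes and fell in 2 (22 and 2 adjusted over the list alone). The gene described as parC, mRNA_XM_002337865, rose at least 7.13-fold (2.91 ± 0.26) and POPTR_0002s20880 by 1.70 ± 0.14. The list was called upward (adjusted p = 1.04e-05, but adjusted p = 0.169 with an estimated correlation).

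Lists of pathogenesis-related, wall and sugar genes were called downward with temperature. Of 204 pathogenesis-related proteins, 53 fell and 9 rose (61 and 15 adjusted over the list alone). The list was called downward (median -0.26, adjusted p = 6.78e-06, and adjusted p = 0.0452 with an estimated correlation). Endochitinase PR4, EST_DN493331(C), which digests fungal chitin, changed by -2.25 ± 0.16, and a thaumatin-like protein, POPTR_0001s09000, by -2.41 ± 0.21. Of 128 genes of starch and sugar metabolism and transport, 33 fell and 7 rose (40 and 10 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.0452 with an estimated correlation), with the sugar transporter ERD6, POPTR_0013s02870, at least 2.77-fold lower (-1.95 ± 0.23). A list of xylem and secondary wall markers was included because a leaf sample holds veins. Its pattern takes any cellulose synthase, laccase, fasciclin or COBRA gene, so it does not measure the share of veins. This list fell in 35 of 108 genes and rose in 1 (47 and 2 adjusted over the list alone, median -0.45, camera adjusted p = 2.26e-10, and adjusted p = 0.0452 with an estimated correlation). A cellulose synthase, EST_CF227502, changed by -1.09 ± 0.15. Of 235 genes of the growing wall 65 fell and 7 rose (82 and 12 adjusted over the list alone; adjusted p = 3.05e-07, but adjusted p = 0.169 with an estimated correlation), with the polygalacturonase POPTR_0011s16230 at -0.99 ± 0.11. Epidermis and cuticle markers fell in 17 of 92 genes and rose in 1 (20 and 1 adjusted over the list alone; adjusted p = 8.74e-06, but adjusted p = 0.169 with an estimated correlation). The ketoacyl-CoA synthases POPTR_0008s11920 and POPTR_0006s26530, which lengthen wax fatty acids, changed by -0.87 and -0.83. These markers of other cell types moved on the same arrays as the wall and sugar lists.

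Photosystem and light-harvesting genes were called downward with temperature (9 of 241 fell and 2 rose, 5 and 2 adjusted over the list alone; adjusted p = 0.0328, but adjusted p = 0.818 with an estimated correlation), with a light-harvesting protein, POPTR_0014s02960, at -1.13. Over all probes 2678 of 34650 were called lower, a larger share than among the photosystem genes. The other 18 lists were not called with temperature. Salicylic acid genes rose in 2 of 14 and fell in 0 (4 and 1 adjusted over the list alone), and WRKY transcription factors, regulators of defence genes, rose in 8 of 93 and fell in 1 (6 and 1 adjusted over the list alone). Phloem and storage markers rose in 9 of 29 and fell in 3 (10 and 5), dividing-cell markers fell in 32 of 290 and rose in 7 (28 and 6), and UDP-glycosyltransferases rose in 29 of 189 and fell in 18 (41 and 19), each pair in brackets being adjusted over the list alone. Numbers that rose and fell, with those adjusted over the list alone in brackets, were 16 and 31 (11 and 24) of 376 leucine-rich repeat and disease resistance genes, 9 and 12 (7 and 9) of 211 antioxidant enzymes, 9 and 4 (9 and 5) of 91 carbon fixation genes, and 4 and 9 (4 and 10) of 61 shikimate pathway genes. They were 21 and 24 (23 and 25) of 217 phenylpropanoid genes, 3 and 7 (2 and 4) of 88 jasmonate genes, 13 and 10 (13 and 9) of 174 ethylene genes, 22 and 34 (25 and 41) of 245 auxin genes and 8 and 22 (9 and 23) of 143 abscisic acid genes. They were 2 and 2 (2 and 2) of 30 clock genes, 22 and 27 (11 and 18) of 778 ribosomal proteins, and 45 and 30 (38 and 22) of 671 ubiquitin and proteasome genes. For sulfur assimilation genes they were 3 and 3 (3 and 3) of 58, a list whose median was -0.01 while its mean was 0.03 and its test pointed upward.

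In total 5177 probes were called for the averaged temperature effect, 2499 higher and 2678 lower. With normexp background correction 3162 were called and 35.8% of them were higher, against 48.3% with the processed signal. With a slide block 8043 were called, among them 5015 of the 5177 in the same direction. Without the arrays of slides 3 to 5, left out after the data were seen, 1175 were called. Within single slides 99.3% (slide 1), 99.8% (slide 2) and 87.9% (slide 3) of the called probes had the sign of the pooled effect. These slides hold arrays that made the calls, so that agreement was partly built in and is no independent check. All arrays of F10 stood on slides 3 to 5, so the count without these slides averages over the other genotypes. The 20 genes named for this effect had the same sign in each of these slides, which the rule that named them required. The photosystem list had a median of 0.01 within slide 2, and the heat shock factor list was not called with slide as a block (adjusted p = 0.0587). Leaving out 1 array ended the call of the heat shock factors for F52 at high temperature replicate 2 (0.0583), I6 at normal temperature replicate 1 (0.0534) and WT at normal temperature replicate 1 (0.0603), and that of the photosystem list for 9 of the 20 arrays, with adjusted p up to 0.292 without WT at high temperature replicate 2.

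The response of each genotype to high temperature was compared next (2 arrays against 2). POPTR_0012s02930, the chloroplastic small heat shock protein, rose in all 5, by 9.04 ± 1.25 in F10 and at least 253-fold in WT (7.98 ± 1.25), 545-fold in F52, 305-fold in I6 (8.91 ± 1.25) and 278-fold in N31 (8.12 ± 1.25). The 18.2 kDa protein POPTR_0010s20300 rose by 4.89 ± 0.63 in WT, 8.48 ± 0.63 in F10, 6.60 ± 0.63 in F52, 4.67 ± 0.63 in I6 and 5.15 ± 0.63 in N31. In WT, bark storage protein B rose at least 74.3-fold (6.22 ± 1.37), the EG45-like protein POPTR_0018s10730 fell at least 50.1-fold (-5.65 ± 0.67), and endochitinase PR4, POPTR_0019s12360, fell at least 32.5-fold. HPTII was among the 5 largest rises of WT, at least 16.7-fold, although it is a vector marker. In F10 the co-chaperone BAG6, POPTR_0002s16790, rose at least 195-fold (7.61 ± 0.41), and gibberellin 20-oxidase, POPTR_0001s17620, an enzyme of gibberellin synthesis, fell at least 16.5-fold (-4.69 ± 0.72). In F52, 4 casbene synthase genes, for enzymes of diterpene synthesis, fell, among them POPTR_0019s06210 at -3.44 ± 0.45. In I6 the EG45-like protein fell at least 45.2-fold, and in N31 the ammonium transporter POPTR_0019s01470 fell at least 10.9-fold (-3.45 ± 0.50).

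Small heat shock proteins were called upward in every genotype (camera adjusted p from 4.25e-44 in F52 to 2.25e-07 in WT). With an estimated correlation their call remained in F10 (adjusted p = 0.0375 with an estimated correlation) and F52 (adjusted p = 0.00366 with an estimated correlation) and was lost in WT (0.298), I6 (0.0977) and N31 (0.121). Of 54 members, 10 rose in WT, 27 in F10, 26 in F52, 7 in I6 and 3 in N31, and 25, 32, 34, 25 and 19 did when adjusted over the list alone. Xylem and secondary wall markers were called downward in N31 (0 of 108 over all probes, 22 adjusted over the list alone; adjusted p = 8.61e-19, and adjusted p = 0.0296 with an estimated correlation). Camera called 9 lists in WT, 14 in F10, 17 in F52, 12 in I6 and 16 in N31, and with an estimated correlation 0, 1, 2, 0 and 1 (in WT and I6 4 and 6 at an unadjusted p under 0.05).

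The temperature effect took in 505 probes in WT (352 higher, 153 lower), 344 in F10 (148 and 196), 327 in F52 (244 and 83), 28 in I6 (13 and 15) and 17 in N31 (9 and 8). These counts rested on single arrays: WT had 0 without replicate 1 at high temperature (2742 at an unadjusted p under 0.05) and 50 and 80 without replicates 1 and 2 at normal temperature, and F10 had 86 without replicate 2 at high and 77 without either replicate at normal temperature. F52 had 214 without replicate 2 at high and 209 and 172 without replicates 1 and 2 at normal temperature. I6 had 4 without replicate 2 at high and 131 and 8 without those at normal temperature, and N31 had 2 without either replicate at high and 10 and 1 without those at normal temperature. The lone array left in a group was assumed to vary like the other groups. A slide block gave 16 in WT, 61 in F10, 18 in I6 and 0 in N31 (2986 at an unadjusted p under 0.05). With normexp they were 66 in WT, 14 in I6 and 11 in N31, and the share higher was 57.6% in WT (69.7% with the processed signal), 71.4% in I6 (46.4%) and 90.9% in N31 (52.9%). Quantile normalization gave 55.3% in F10 (43.0%). Normexp moved the median of all probes in the WT comparison by -0.15. Of the 10 genes named per genotype, 0 in WT, 5 in F10, 9 in F52, 0 in I6 and 0 in N31 kept their call whichever array was left out.

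Whether the lines differed from WT in their response was tested as an interaction (8 arrays). In F10, BAG6, a co-chaperone of the heat response, rose by 7.61 against 2.40 in WT, a difference of 5.20 ± 0.58 (adjusted p = 0.011). The V-type proton ATPase subunit E gene POPTR_0016s14660 changed by -3.68 in F10 and -0.14 in WT (difference -3.54 ± 0.38), and the calcium-binding protein CML41, POPTR_0005s12930, by -2.47 and 0.29 (difference -2.76 ± 0.37). In F52, a pair of farnesene synthase genes, which make a leaf volatile, changed in the opposite direction to WT: POPTR_0011s03440 by 2.96 against -2.63 (difference 5.59 ± 0.66, adjusted p = 0.0376) and mRNA_XM_002337445 by 3.01 against -2.62 (difference 5.63 ± 0.80). NAC domain protein 69 genes POPTR_0014s10360 and POPTR_0014s10330 differed by 4.51 ± 0.59 and 4.37 ± 0.62, and the transcription factor bHLH71, POPTR_0001s02350, by -2.74 ± 0.38. Small heat shock proteins rose more in F10 (12 of 54 adjusted over the list alone, 0 over all probes; adjusted p = 1.65e-11, but adjusted p = 0.266 with an estimated correlation) and in F52 (17 of 54 adjusted over the list alone, 0 over all probes; adjusted p = 1.32e-18, but adjusted p = 0.0728 with an estimated correlation) than in WT. Limma called 0 of the 241 photosystem genes in the difference for F10, over all probes or adjusted over the list alone (56 lower and 0 higher at an unadjusted p under 0.05). Their list was called downward by camera (median -0.79, adjusted p = 2.68e-11, but adjusted p = 0.466 with an estimated correlation). Camera called 9 lists for F10, 13 for F52, 3 for I6 and 3 for N31, and with an estimated correlation 0 in each (2, 6, 0 and 0 at an unadjusted p under 0.05).

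Limma called 3 probes for F10 (1 higher, 2 lower) and 7 for F52 (5 higher, 2 lower). For I6 and N31 it called 0, with 1078 and 1571 probes at an unadjusted p under 0.05. The calls rested on single arrays: the F10 count was 6 without F10 at high temperature replicate 1, 36 without WT at high temperature replicate 2 and 0 without F10 at high temperature replicate 2, F10 at normal temperature replicate 2 or any of the other 3 WT arrays (2126 to 4243 at an unadjusted p under 0.05). The F52 count was 75 without F52 at high temperature replicate 1, 13 without F52 at normal temperature replicate 2 and 0 without either of its other arrays or any of the 4 WT arrays (1892 to 3932 at an unadjusted p under 0.05). Leaving out 1 array gave up to 69 for I6 (without its replicate 1 at normal temperature; 3 without its replicate 2 at high temperature) and up to 11 for N31 (without WT at high temperature replicate 2). Limma with a slide block called 0 probes for F10 (2340 at an unadjusted p under 0.05) and 0 for F52 (3926). The share higher was 33.3% for F10 and 50% with quantile or median scaling and 16.7% with normexp, and for F52 71.4% and 100% with quantile scaling or normexp. Normexp moved the median of all probes by 0.14 for I6 and 0.11 for N31.

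The 3 Irp9 lines were compared with WT over both temperatures to ask what salicylate synthase changes (12 arrays against 4). Among the largest rises, chalcone synthase, POPTR_0003s17530, the entry step of flavonoid synthesis, rose at least 10.4-fold (3.55 ± 0.44, adjusted p = 6.91e-04), leucoanthocyanidin dioxygenase, POPTR_0001s08410, rose 9.30-fold (3.22 ± 0.58), and naringenin 3-dioxygenase, POPTR_0005s11580, rose at least 3.96-fold. The phenylpropanoid and flavonoid list was not called (28 of 217 rose and 13 fell, 29 and 16 adjusted over the list alone; adjusted p = 0.373). Among WRKY factors, WRKY18, POPTR_0006s27950, was higher by 4.25 ± 0.27 (adjusted p = 4.24e-06), WRKY40, POPTR_0018s02480, by 3.92 ± 0.35 and WRKY51, POPTR_0005s08720, by 3.79 ± 0.29. These 3 averages came from F10 and F52: in I6 the genes were not called, and WRKY18 changed by 0.05 at normal and 0.19 at high temperature. EPFL9, POPTR_0002s25140, a peptide that promotes stomata, changed by -2.12 ± 0.28 (adjusted p = 1.14e-03). It was lowest in F10 (-3.34 at normal and -4.99 at high temperature) and was not called in I6 (-0.87 and -0.32), nor were chalcone synthase and POPTR_0001s08410 called there. A pair of anthocyanidin 3-O-glucosyltransferases, POPTR_1038s00210 and POPTR_0016s01840, changed by -2.73 ± 0.24 and -2.70 ± 0.22. The last 2 averages came mainly from F52, where at normal temperature they were at least 152-fold and 166-fold lower (-7.75 and -7.38), against -1.01 and -0.98 in F10, which were not called.

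The list results of this comparison are averages over the Irp9 lines. Against WT, I6 had only 15 called probes at normal and 4 at high temperature. A called list therefore does not show a change in each line. WRKY transcription factors rose in 26 of 93 genes and fell in 0 (33 and 0 adjusted over the list alone, median 0.52, camera adjusted p = 5.30e-12, but adjusted p = 0.146 with an estimated correlation). Salicylic acid genes rose in 6 of 14 (6 adjusted over the list alone), among them the regulator NPR1, POPTR_0012s11900, at 1.35 ± 0.21 (adjusted p of the list 0.00269, but adjusted p = 0.348 with an estimated correlation). Leucine-rich repeat and disease resistance genes rose in 70 of 376 and fell in 6 (92 and 11 adjusted over the list alone; adjusted p = 7.59e-09, but adjusted p = 0.271 with an estimated correlation), with the receptor kinase POPTR_0011s11330 at 1.85 ± 0.17. Jasmonate and wound genes rose in 11 of 88 and fell in 4 (15 and 8 adjusted over the list alone; adjusted p = 0.0488, but adjusted p = 0.48 with an estimated correlation), with a polyphenol oxidase, POPTR_0001s39950, at 1.87 ± 0.32. Pathogenesis-related proteins were not called as a list (31 of 204 rose and 14 fell, 33 and 19 adjusted over the list alone; adjusted p = 0.228), although basic PR1, POPTR_0001s29530, rose by 2.64 ± 0.41. Auxin genes fell in 41 of 245 and rose in 9 (46 and 12 adjusted over the list alone; adjusted p = 0.0167, but adjusted p = 0.146 with an estimated correlation), with the SAUR gene POPTR_0004s17150 at -1.55 ± 0.18. Growing-wall genes fell in 30 of 235 and rose in 15 (44 and 16 adjusted over the list alone; adjusted p = 0.00881, but adjusted p = 0.745 with an estimated correlation), with expansin-A8, POPTR_0019s08570, which loosens walls, at -1.12.

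Antioxidant enzymes were called downward (22 of 211 fell and 14 rose, 32 and 16 adjusted over the list alone; adjusted p = 0.00847, but adjusted p = 0.745 with an estimated correlation), as were ribosomal proteins (38 of 778 fell and 13 rose, 19 and 9 adjusted over the list alone; adjusted p = 8.71e-04, but adjusted p = 0.767 with an estimated correlation). Over all probes 1844 of 34650 were called lower, a share no smaller than that among the ribosomal proteins. Markers of other cell types moved on the same arrays. Xylem and secondary wall markers rose in 25 of 108 genes and fell in 4 (30 and 9 adjusted over the list alone; adjusted p = 3.84e-04, but adjusted p = 0.348 with an estimated correlation), among them cellulose synthase CesA7, POPTR_0006s19580, at 1.40 ± 0.20. Epidermis and cuticle markers fell in 16 of 92 and rose in 2 (17 and 3 adjusted over the list alone; adjusted p = 8.52e-05, but adjusted p = 0.348 with an estimated correlation). The remaining 18 lists were not called in this comparison.

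For the Irp9 lines 4357 probes were called, 2513 higher and 1844 lower. Without WT at high temperature replicate 2 there were 1213, without WT at normal temperature replicate 2 there were 1238, and 876 without F10 or 454 without the arrays of slides 3 to 5, both left out after the data were seen. Normexp gave 2387 and quantile scaling ended the calls of the antioxidant (adjusted p = 0.137) and ribosomal (0.244) lists. The share higher was 57.7%, 46.3% with median centring and 46.6% with normexp. With slide as a block 3167 of the called probes were called again, and the jasmonate list was lost (adjusted p = 0.0589). Within slide 1, 93.0% of called probes had the pooled sign and within slide 2, 98.3%. Arrays of both slides also made the calls, so this agreement was partly built in. Neither slide holds an array of F10. These shares and the count without slides 3 to 5 therefore have F52 and I6 as the Irp9 lines. Medians within slides had the other sign for salicylic acid genes (-0.04, slide 1), leucine-rich repeat genes (-0.02, slide 1) and growing-wall genes (0.08, slide 2). Without WT at normal temperature replicate 1 the auxin (0.161) and growing-wall (0.236) calls ended, without WT at normal temperature replicate 2 the antioxidant (0.081) and ribosomal (0.187) calls ended, and the jasmonate call ended without any 1 of 9 arrays (adjusted p up to 0.161, without WT at high temperature replicate 1).

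Plastidic and cytosolic Irp9 were set against each other to ask whether the site of synthesis matters (8 arrays of F10 and F52 against 4 of I6, no WT array). I6 was the only cytosolic line and had less Irp9 signal, so site, line and transgene level cannot be told apart here. Among the genes higher in the plastidic lines, WRKY18, POPTR_0006s27950 (named above), differed 73.8-fold (6.21 ± 0.28, adjusted p = 3.75e-07), WRKY40 by 5.91 ± 0.37, WRKY51 by 5.34 ± 0.30, and the pathogenesis-related protein EST_CV282559(C), a marker of salicylic acid responses, by 4.68 ± 0.39 (adjusted p = 1.34e-05). For that protein F52 at normal temperature had a mean of -1.69 ± 1.23 (SD, n = 2), near WT at -1.88, while F10 had 2.57. At high temperature F52 and F10 had -0.62 and 1.85 against -3.98 in WT. I6 lay below WT at both temperatures (-3.01 at normal and -5.29 at high). An anthocyanin 5-O-glucosyltransferase, POPTR_0006s05450, was at least 147-fold higher (7.51 ± 0.94), though its 2 arrays of F52 at normal temperature lay far apart (mean -0.85, SD 3.99). A patatin, POPTR_0019s03090, which cleaves lipids, was at least 30.1-fold higher. External NADH-ubiquinone oxidoreductase, POPTR_0013s14340, was at least 7.04-fold lower (-3.28 ± 0.58), and metallothionein type 2, EST_CV237444(C), which binds metal ions, was lower by -2.47 ± 0.37.

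**Figure D3:**
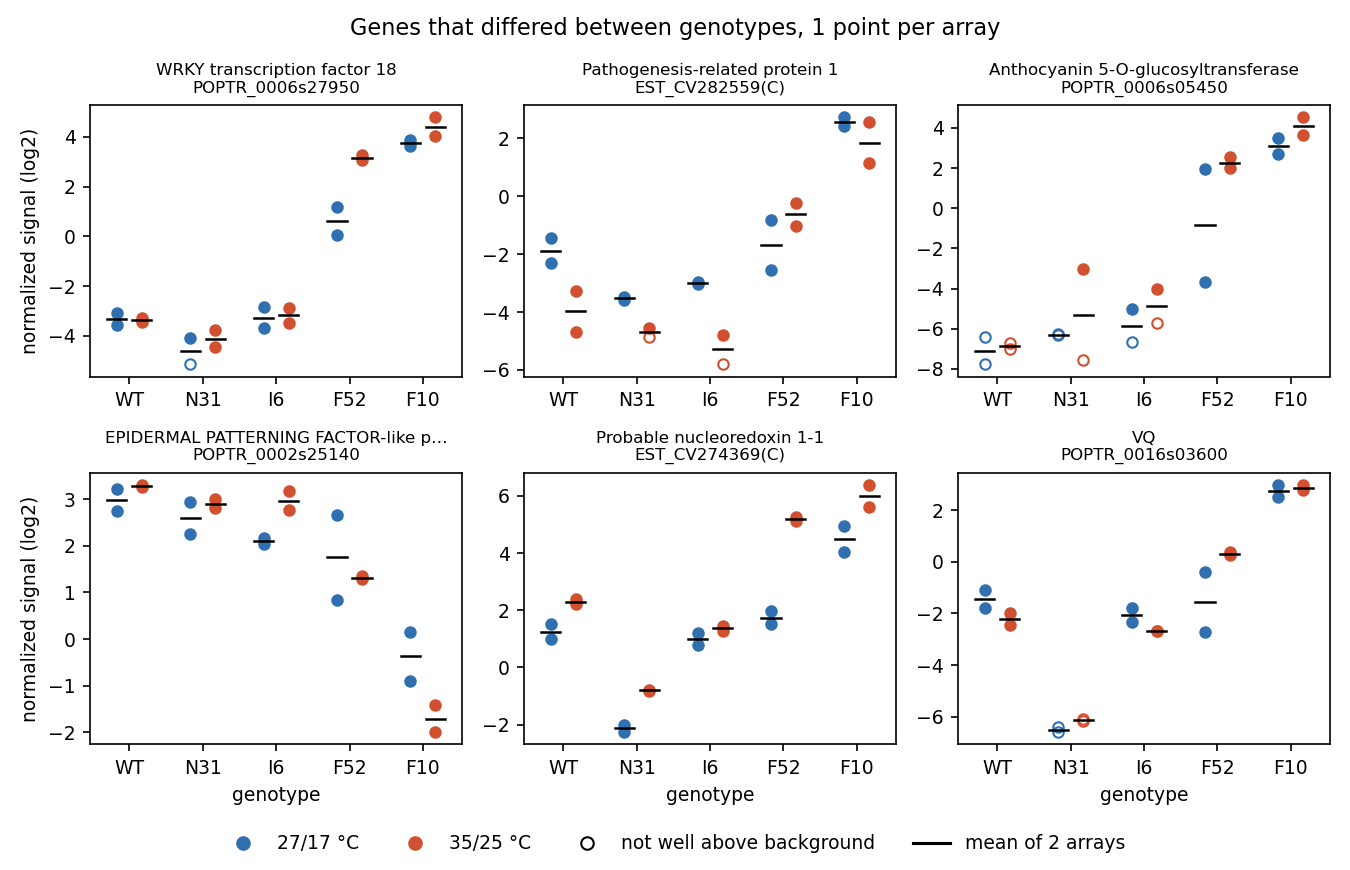
Normalized log2 signal (vertical axes) of 6 genes named for genotype differences, by genotype (horizontal axes), 1 point per array and a line for the mean of 2 arrays, with open points not well above background. WRKY18 had group means of 0.62 to 4.40 in F52 and F10 and of -4.61 to -3.18 in the other 6 groups, and nucleoredoxin 1-1 had means of -2.14 and -0.80 in N31 and at least 0.98 in the other 8 groups.

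WRKY transcription factors were higher in 28 of 93 genes and lower in 0 (33 and 0 adjusted over the list alone; adjusted p = 3.31e-12, but adjusted p = 0.109 with an estimated correlation). Salicylic acid genes were higher in 5 of 14 (6 adjusted over the list alone; median 0.72, adjusted p = 4.37e-04, but adjusted p = 0.229 with an estimated correlation), with NPR1, POPTR_0015s12580, at 1.41 ± 0.21. Pathogenesis-related proteins were higher in 42 of 204 and lower in 13 (47 and 16 adjusted over the list alone; adjusted p = 8.02e-04, but adjusted p = 0.219 with an estimated correlation), with a list median of 0.13 that was -0.08 with normexp. Leucine-rich repeat genes were higher in 60 of 376 and lower in 7 (77 and 12 adjusted over the list alone; adjusted p = 1.58e-05, but adjusted p = 0.273 with an estimated correlation), with a median of 0.17 that was -0.04 with normexp. Jasmonate genes were higher in 20 of 88 and lower in 1 (28 and 6 adjusted over the list alone; adjusted p = 1.92e-05, but adjusted p = 0.109 with an estimated correlation), with polyphenol oxidase POPTR_0001s39950 at 2.44 ± 0.34. Glutathione S-transferases were higher in 18 of 70 and lower in 1 (27 and 7 adjusted over the list alone; adjusted p = 2.87e-05, but adjusted p = 0.273 with an estimated correlation), with POPTR_0010s07150 at 1.59 ± 0.20. Small heat shock proteins were higher in 8 of 54 and lower in 1 (17 and 2 adjusted over the list alone; adjusted p = 4.26e-06, but adjusted p = 0.273 with an estimated correlation), with POPTR_0019s11060 at 1.53 ± 0.29. Phenylpropanoid genes were higher in 30 of 217 and lower in 12 (40 and 16 adjusted over the list alone; adjusted p = 0.0401, but adjusted p = 0.331 with an estimated correlation), with a median of 0.07 that was -0.06 with normexp.

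Lists of growth and photosynthesis genes were called lower in the plastidic lines, though few members of the photosynthesis lists were called. Over all probes 1592 of 34650 were called lower. Growing-wall genes were lower in 37 of 235 and higher in 14 (48 and 17 adjusted over the list alone; adjusted p = 0.00793, but adjusted p = 0.451 with an estimated correlation), with expansin-A8 at -1.38. Auxin genes were lower in 30 of 245 and higher in 10 (39 and 13 adjusted over the list alone; adjusted p = 0.0423, but adjusted p = 0.219 with an estimated correlation). Photosystem genes were lower in 9 of 241 and higher in 0 (1 and 0 adjusted over the list alone; adjusted p = 0.00796, but adjusted p = 0.724 with an estimated correlation), with the light-harvesting protein EST_CV282202(C) at -1.02. Carbon fixation genes were lower in 3 of 91 (0 adjusted over the list alone; adjusted p = 0.00136, but adjusted p = 0.5 with an estimated correlation). Of the markers of other cell types, xylem and secondary wall genes were higher in 17 of 108 and lower in 2 (20 and 2 adjusted over the list alone; adjusted p = 0.00384, but adjusted p = 0.331 with an estimated correlation), with laccase-4, POPTR_0010s20050, at 1.79 and a list median of 0.16 that was -0.01 with normexp. Epidermis and cuticle markers were lower in 12 of 92 and higher in 0 (13 and 0 adjusted over the list alone; adjusted p = 0.00113, but adjusted p = 0.331 with an estimated correlation).

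Between plastidic and cytosolic Irp9, 3570 probes were called, 1978 higher and 1592 lower. The share higher was 55.4%, and 48.8% with normexp. The count was 2367 without F10 at normal temperature replicate 1, 2220 and 1776 without replicates 1 and 2 of I6 at high temperature, 1969 and 2265 without those of I6 at normal temperature, and 771 without the arrays of slides 3 to 5. With slide as a block 1171 were called, 1057 of them in common with the same sign. Of the 10 genes named, 9 kept their call, POPTR_0013s14340 did not (-2.44, adjusted p = 0.101), and the phenylpropanoid (0.0564) and growing-wall (0.0629) lists were lost. Within slide 1, 99.0% and within slide 2, 95.8% of called probes had the pooled sign, which is partly built in, as arrays of both slides made the calls. Neither slide holds an array of F10. These shares and the count without slides 3 to 5 therefore compare F52 alone with I6. List medians of the other sign within a slide were 0.19 for the growing wall and 0.12 for the epidermis in slide 2 and -0.13 for phenylpropanoid genes in slide 1. Quantile scaling ended the calls of the photosystem (0.597), carbon fixation (0.0546), phenylpropanoid (0.0515) and auxin (0.0515) lists, and normexp that of the photosystem list (0.1). Leaving out 1 array ended the phenylpropanoid call for 7 of the 12 arrays, the auxin call for 6 and the photosystem call for 3 (adjusted p up to 0.213, 0.0977 and 0.429). It also ended the carbon fixation call without I6 at normal temperature replicate 1 (0.0624), the growing-wall call without F52 at high temperature replicate 1 (0.0757) and the xylem call without I6 at high temperature replicate 2 (0.0671).

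The NahG line was compared with WT over both temperatures to ask what loss of salicylic acid changes (4 arrays against 4). N31 was the only NahG line, and the arrays do not measure salicylic acid. Loss of salicylic acid, the catechol formed and the line itself therefore cannot be told apart. NahG itself was at least 564-fold higher (9.63 ± 0.63, adjusted p = 1.57e-05). A calcium-binding EF-hand protein, EST_Contig328, was lower by -4.67 ± 0.48, nucleoredoxin 1-1, EST_CV274369(C), a thioredoxin-like protein, by -3.24 ± 0.24 (adjusted p = 5.13e-05), and a gene with a VQ motif, POPTR_0016s03600, a kind of protein that binds WRKY factors, was at least 12.5-fold lower. WRKY70, POPTR_0006s10950, which acts in salicylic acid signalling, was lower by -2.14 ± 0.35, and a basic pathogenesis-related protein, EST_CK094766(C), by -1.98 ± 0.22. The RNA-binding protein POPTR_0011s14630 was at least 6.31-fold higher (2.95 ± 0.39) and the polyol transporter EST_DB885543 at least 5.09-fold higher (2.67 ± 0.27).

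Glutathione S-transferases were lower in 5 of 70 genes and higher in 0 (10 and 0 adjusted over the list alone; adjusted p = 0.0444, but adjusted p = 0.8 with an estimated correlation), with POPTR_0001s42760 at -1.16 ± 0.19. Antioxidant enzymes were lower in 10 of 211 and higher in 4 (21 and 7 adjusted over the list alone; adjusted p = 0.0155, but adjusted p = 0.8 with an estimated correlation), with glutathione peroxidase EST_sc1-Contig2892(C) at -1.31. Small heat shock proteins were called downward (median -0.50, adjusted p = 0.00263, but adjusted p = 0.8 with an estimated correlation) although limma called 0 of the 54 genes, over all probes or adjusted over the list alone. Pathogenesis-related proteins (8 of 204 lower, 3 higher; 6 and 1 adjusted over the list alone; adjusted p = 0.242), WRKY factors (5 of 93 lower, 5 higher; 5 and 6 adjusted over the list alone; adjusted p = 0.261) and salicylic acid genes (1 of 14 lower, 1 higher, also when adjusted over the list alone; adjusted p = 0.61) were not called as lists. Of the 786 probes lower in the NahG line, 202 were called higher in the plastidic against cytosolic comparison, where 44.9 would be shared by chance, and 39 were called lower (36.1 by chance). Of the 1383 probes higher in it, 48 were called lower (63.5 by chance) and 47 higher (78.9 by chance), so the overlap had no counterpart in that set.

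For the NahG line 2169 probes were called, 1383 higher and 786 lower. The count was 98 and 834 without replicates 1 and 2 of N31 at high temperature, 246 without replicate 1 of N31 at normal temperature, 151 without WT at high temperature replicate 2 and 299 without WT at normal temperature replicate 2, and 1016 without the arrays of slides 3 to 5. Normexp gave 364, with 52.2% higher against 63.8%, and a fit of group means to the 8 arrays alone gave 14. Quantile scaling (0.111 and 0.145) and the slide block (0.199 and 0.0933) ended the calls of the glutathione S-transferase and antioxidant lists. With slide as a block 792 probes were called, 635 of them in common with the same sign, and the ABC transporter EST_BI130736(C) (adjusted p = 0.0543) and the amino acid transporters POPTR_0004s18770 (0.0611) and POPTR_0014s18020 (0.0672) lost their calls. Within slides 1 and 2, 99.8% of called probes had the pooled sign, but arrays of these slides also made the calls, so the agreement was partly built in. Leaving out 1 array ended the glutathione S-transferase call for 4 of the 8 arrays (N31 at high and normal temperature replicate 2, WT at high and normal temperature replicate 1; adjusted p up to 0.271) and the antioxidant call without WT at high temperature replicate 1 (0.0656). Of the 10 genes named, 7 kept their call whichever array was left out.

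Each line was also set against WT at 1 temperature (2 arrays against 2). At normal temperature F10 had at least 491-fold more of the anthocyanin 5-O-glucosyltransferase POPTR_0006s05450 and at least 132-fold less of expansin-B2, POPTR_0014s06170. F52 had at least 22.6-fold more of the calcium-binding protein CML37, POPTR_0002s00350, and at least 171-fold less of an anthocyanidin 3-O-glucosyltransferase, POPTR_0545s00210. In I6 an F-box protein, POPTR_0008s18000, was at least 6.22-fold higher and the polyol transporter EST_DB885543 at least 5.82-fold higher. In N31 the ALIX-like protein POPTR_0008s12580, of a family that sorts cargo in endosomes, was at least 11.7-fold higher and the EF-hand protein EST_Contig328 at least 38.2-fold lower (-5.26 ± 0.68). WRKY factors were higher in 26 of 93 genes in F10 and in 13 in F52 (30 and 28 adjusted over the list alone; adjusted p = 3.29e-07 and 1.72e-08, but adjusted p = 0.598 and 0.557 with an estimated correlation). Growing-wall genes were lower in F10 in 36 of 235 genes (51 adjusted over the list alone; adjusted p = 0.0017, but adjusted p = 0.598 with an estimated correlation). Camera called 5 lists in F10, 4 in F52, 2 in I6 and 4 in N31, and with an estimated correlation 0 in each (1, 1, 0 and 0 at an unadjusted p under 0.05).

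At high temperature POPTR_0006s05450 was at least 1282-fold higher in F10 and at least 363-fold higher in F52, and a second 5-O-glucosyltransferase, POPTR_0016s05290, at least 884-fold (9.79 ± 1.47) and 617-fold (9.27 ± 1.47). Monothiol glutaredoxin-S6, EST_CV283601(C), a redox protein, was at least 55.0-fold lower in F10 (-6.34 ± 1.15). In N31 nucleoredoxin 1-1 was lower by -3.09 ± 0.34 and its relatives POPTR_0010s06930 and POPTR_0010s06980 by -2.79 ± 0.37 and -2.49 ± 0.36. The 4 probes called in I6 were Irp9, HPTII, mGFP5 and rsGFP, the last 3 being vector markers. The mGFP5 probe lies outside the rule for named genes and was chosen after its value was seen. Leucine-rich repeat and disease resistance genes were higher in 57 of 376 in F10 and 51 in F52 (82 and 73 adjusted over the list alone; adjusted p = 7.83e-11 and 8.68e-15, but adjusted p = 0.168 and 0.0779 with an estimated correlation). Auxin genes were lower in 53 of 245 in F10 (73 adjusted over the list alone; adjusted p = 4.51e-04, and adjusted p = 0.0483 with an estimated correlation). Camera called 16 lists in F10, 16 in F52, 8 in I6 and 6 in N31, and with an estimated correlation 1, 0, 0 and 0 (6, 9, 1 and 1 at an unadjusted p under 0.05).

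**Figure D4:**
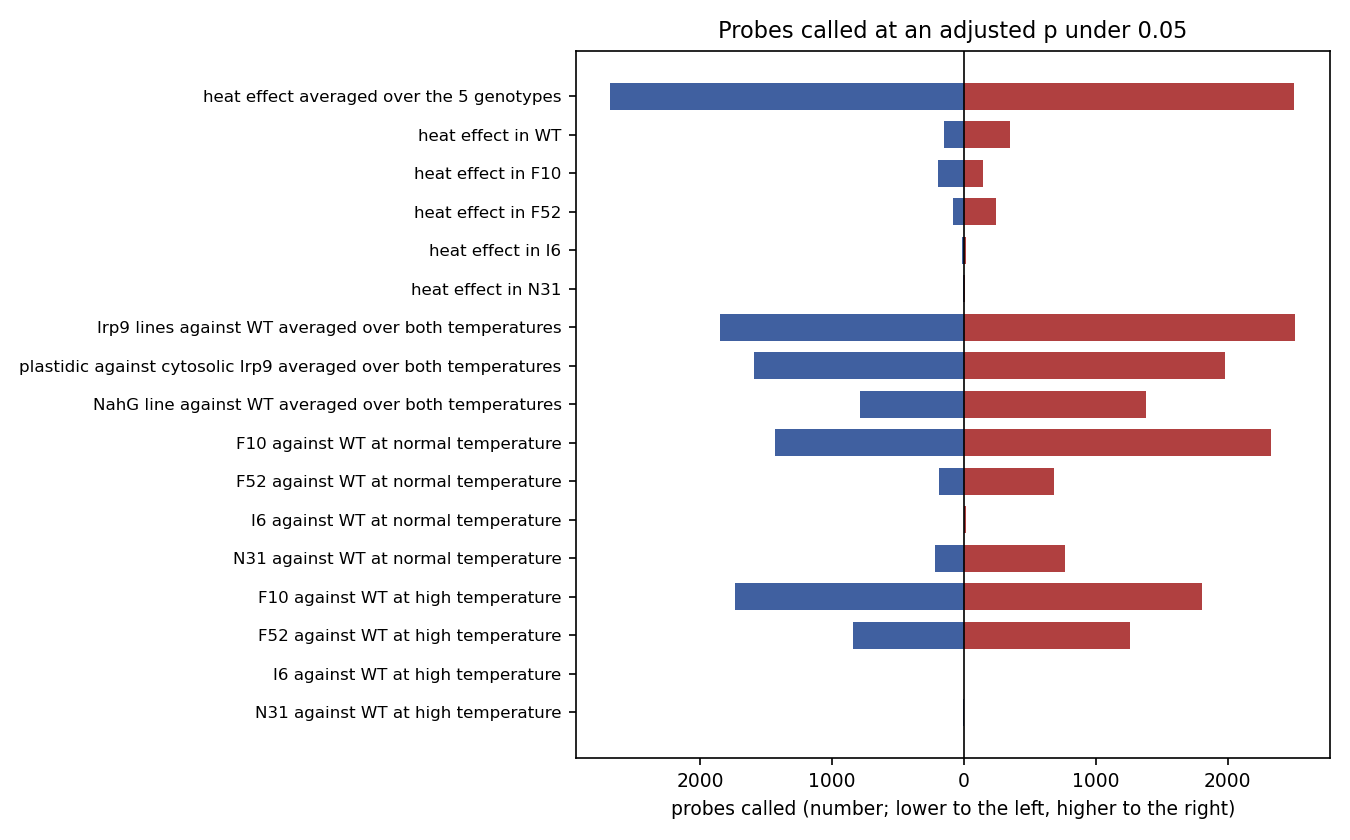
Number of probes called per comparison (horizontal axis; lower to the left, higher to the right) for the averaged effects, the temperature effect in each genotype and each line against WT at each temperature. F10 had 3764 called probes at normal temperature against 15 for I6, and the longer side of the bar changed with at least 1 other scaling for the temperature effect averaged and in F10 and I6, for the Irp9 lines, plastidic against cytosolic Irp9, F10 at high temperature and N31 at both temperatures.

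Against WT at normal temperature 3764 probes were called in F10 (2330 higher), 874 in F52 (685 higher), 15 in I6 (all higher) and 987 in N31 (769 higher). At high temperature there were 3539 in F10 (1804 higher), 2103 in F52 (1262 higher), 4 in I6 (all higher) and 7 in N31 (3 higher). At normal temperature the F10 count was 369 and 1501 without its own replicates 1 and 2 and 1413 and 1375 without those of WT. The F52 count was 128 and 345 without its own and 100 without WT replicate 2, the I6 count was 112 and 7 without its own and 4 without WT replicate 1, and that of N31 was 19 and 635 without its own and 92 without WT replicate 2. At high temperature the F10 count was 1803 and 1521 without its own replicates 1 and 2 and 1728 and 1256 without those of WT. The F52 count was 896 without its own replicate 2 and 653 and 768 without WT replicates 1 and 2, the I6 count was 7 without its own replicate 2, and the N31 count was 1 and 3 without its own and 3 without WT replicate 1. The slide-blocked counts in F10 were 175 and 505 at normal and high temperature (153 and 473 in common with those above), in F52 2422 and 772, in N31 158 and 4, and in I6 8 at normal temperature. The share higher moved with scaling in F10 at normal temperature (61.9%, 50.5% with median centring), F52 at normal temperature (78.4%, 62.5% with normexp), N31 at normal temperature (77.9%, 41.7% with normexp) and N31 at high temperature (42.9%, 60% with quantile scaling, 30% with median centring). Normexp moved the median of all probes in F10 at normal temperature by -0.11. F10 and F52 shared 534 probes of the same direction at normal temperature, 472 higher and 62 lower, where independent lists would share 46.1 and 7.82, and 2 changed in opposite directions. Groups without any change, simulated against the same WT arrays, shared 0 on average and at most 0 over 100 simulations. As almost nothing is called without a change, that value says little about lists of this length. The 2 WT arrays could not be divided between the lines, so part of the overlap may come from the shared arrays. The shared count was 310 and 65 without WT replicates 1 and 2, 254 without F10 replicate 2 and 18.9% of the count with all arrays without F10 replicate 1, 84 and 236 without replicates 1 and 2 of F52, and 129 with the slide block.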

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

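The tests of the vector markers were chosen only after their result was seen; the interaction tests were planned.

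Both WT arrays and both N31 arrays at high temperature, and replicate 1 of N31 at normal temperature, gave signal for HPTII, mGFP5 and rsGFP, markers of the vector of the Irp9 lines, which these plants do not carry by their labels. This is signal outside the comparisons. The mean of the 3 markers lay above WT at normal temperature by 3.61 and 2.82 (log2) in WT replicates 1 and 2 at high temperature, by 4.59 and 3.53 in N31 replicates 1 and 2 at high temperature, and by 3.25 in N31 replicate 1 at normal temperature. On the first of these WT arrays the NahG probe, which reads the transgene of N31, was also well above background, at -4.39.

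A transcript of poplar that rises in heat and binds the marker probes was argued against for the N31 array at normal temperature, which exceeded the higher WT array at that temperature by at least 1.97 on each of the 3 markers. For the arrays at high temperature it stays open: HPTII rose by 4.59 in WT, as such a transcript would, and the pattern and temperature cannot be told apart in WT because both of its arrays at high temperature show it. A share of RNA or labelled material from an Irp9 line in these 5 samples may account for the marker signal. The 3 markers lay about equally far below their Irp9-line means on each array (largest SD 0.556), at 0.148 to 0.504% of that level. Of these, mGFP5 and rsGFP are both green fluorescent protein markers. Their means were close in F52 (6.93 and 7.08), F10 (7.78 and 7.67) and I6 (6.71 and 6.85), so their agreement adds little. Such a share would not bring the NahG signal of WT replicate 1 at high temperature, as no Irp9-line array had NahG well above background. Where such a share would have entered was not tested, and no biological explanation was tested beyond the transcript.

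Differences between lines in the response to temperature came from the interaction tests. Camera called 9 lists for F10, 13 for F52, 3 for I6 and 3 for N31, and limma called 3 probes for F10 and 7 for F52. In F10 the differences from WT were 5.20 for BAG6 (POPTR_0002s16790), -3.54 for V-type proton ATPase subunit E (POPTR_0016s14660) and -2.76 for CML41 (POPTR_0005s12930). In F52 they were 5.63 and 5.59 for the farnesene synthases mRNA_XM_002337445 and POPTR_0011s03440, 4.51 and 4.37 for the NAC69 genes POPTR_0014s10360 and POPTR_0014s10330, and -2.74 for bHLH71 (POPTR_0001s02350). With an estimated correlation camera called 0 lists in each of these 4 comparisons, with 2, 6, 0 and 0 at an unadjusted p under 0.05.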

How the results depend on the processing

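Under the alternatives no called gene among those named changed sign, and no called list changed the direction of its camera test, which compares it with the other genes. The median itself changed sign with normexp in 4 of the 37 called lists, all of plastidic against cytosolic Irp9. Quantile normalization ended the call of 9 of the 37 lists, normexp that of 2 and median centring that of 1, not all of them named above. With each called list counted once per alternative, 382 results stayed past the threshold and 36 did not. A named probe was filed with the lists, so these counts include it. With each named probe counted once per comparison and alternative, 4567 results stayed on their side of the threshold, 56 passed it newly and 602 no longer passed. With 1 array left out, some lists and named probes also lost their call. Counts of called probes moved by more than 1.5 times as given here; unless stated, the cause was not tested. Signal over background limits the dim genes, since 52.3 to 64.8% of spots were well above background. The values of the series table moved no count by that much. Fits without slides 3 to 5, without F10 and within slides were chosen after seeing the data. Those without slides 3 to 5 and within slides 1 and 2 hold no array of F10. In them temperature is averaged over other genotypes, the Irp9 lines are F52 and I6, and plastidic Irp9 is F52 alone. Where limma called 0 probes, 498 to 4944 had an unadjusted p under 0.05, and 423 to 4243 with 1 array left out. Comparisons of a line with WT at normal or high temperature are written as the line with "normal" or "high".

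With normexp the counts were 3162 for the averaged temperature effect, 66, 14 and 11 for that in WT, I6 and N31, 2387 for the Irp9 lines, 364 for the NahG line, 1666, 88, 3 and 12 for F10, F52, I6 and N31 normal, 6 for the F10 difference of the temperature effect, and 41 shared between F10 and F52. Quantile normalization gave 299 and 28 for temperature in WT and N31 and 6 for I6 normal, and median centring gave 7 for I6 normal. Without the filter on dim probes they were 2832 averaged, 17, 112, 149, 5 and 1 for temperature in WT, F10, F52, I6 and N31, 1715 for the Irp9 lines, 1935 for plastidic against cytosolic, 333 for the NahG line, 1405, 177, 5 and 184 for F10, F52, I6 and N31 normal, 1732, 950 and 4 for F10, F52 and N31 high, 0 for the F10 and 0 for the F52 difference, and 108 shared. With only probes well above background on all arrays, 10 and 26 were called for temperature in I6 and N31 and 1 each for I6 normal and high, where fewer probes were tested. Trend and robust settings gave 40 for temperature in N31, 12 for N31 high and 7 for the F10 difference.

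A block for slide gave 8043 averaged, 16, 61, 18 and 0 for temperature in WT, F10, I6 and N31, 1171 for plastidic against cytosolic, 792 for the NahG line, 175, 2422, 8 and 158 for F10, F52, I6 and N31 normal, 505, 772 and 4 for F10, F52 and N31 high, 0 for the F10 and 0 for the F52 difference, and 129 shared. A block for scan gave 8840 averaged, 1084, 876, 706, 126 and 9 for temperature in WT, F10, F52, I6 and N31, 7397 for the Irp9 lines, 1997 for plastidic against cytosolic, 4276 for the NahG line, 1155, 3397 and 52 for F10, F52 and I6 normal, and 34 and 3 for the F10 and F52 differences. Replicate numbers were taken from the sample titles. File names number N31 at normal temperature replicate 2 and WT at high temperature replicate 1 as 3. The labels name no batch shared by same-numbered arrays. Deviations of these arrays from their group means still correlated more often positively (45 pairs, r of -0.19 to 0.56, median 0.18, 27 of them over 0.1). The numbers partly follow the slides, with 7 of 10 first replicates on slide 1 and 7 of 10 second ones on slide 2. Variation that follows replicate number or slide was thus left in the main fit. With the numbers as a block, all 5177 calls of the averaged temperature effect were kept and 6874 were called. The counts that moved were 1107, 551, 497, 70 and 39 for temperature in WT, F10, F52, I6 and N31. They were 4236 for the NahG line and 5862, 2041, 39 and 2302 for F10, F52, I6 and N31 normal. They were 3284 for F52 high, 8 for the F10 difference and 1261 shared. With only the arrays of the groups compared, which leaves fewer arrays for the spread, they were 0, 22, 1, 129 and 0 for temperature in WT, F10, F52, I6 and N31, 14 for the NahG line, 5, 5 and 0 for F52, I6 and N31 normal, 1195, 57 and 0 for F10, F52 and N31 high, 0 for the F10 and 0 for the F52 difference, and 39 shared. Without slides 3 to 5, which leaves fewer arrays, 1175 were called for averaged temperature, 454 for the Irp9 lines, 771 for plastidic against cytosolic and 1016 for the NahG line, and without F10 876 for the Irp9 lines. Within slide 1, 2, 0 and 0 were called for averaged temperature, the Irp9 lines and plastidic against cytosolic, and within slide 2 1, 5 and 4.

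Leaving out 1 array at a time gave 3630 to 5802 averaged, 0 to 701, 77 to 250, 172 to 454, 4 to 131 and 1 to 10 for temperature in WT, F10, F52, I6 and N31, 1213 to 4905 for the Irp9 lines, 1776 to 4161 for plastidic against cytosolic and 98 to 3131 for the NahG line. It gave 369 to 1501, 100 to 624, 4 to 112 and 19 to 972 for F10, F52, I6 and N31 normal, 1256 to 1803, 653 to 2013, 3 to 7 and 1 to 6 for them high, 0 to 36, 0 to 75, 0 to 69 and 0 to 11 for their differences, 65 to 310 shared, and 33 to 40 lists called over the 4 averaged comparisons against 37. Fits in which a group kept 1 array assume that it varies like the other groups.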

Other observations

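The split test of lists with an estimated correlation and the spread required of the tests of the graded response and of slides, and the tests of that response in F52 and I6 by temperature, were chosen after first results were seen; the other tests were written before.

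Further lists were called in comparisons of 1 genotype or line. In the temperature effect of F10, photosystem genes were called downward (median -0.62, adjusted p = 1.44e-10, but adjusted p = 0.402 with an estimated correlation), with 2 of 241 genes lower and 0 higher, and 2 and 0 when adjusted over the list alone. Carbon fixation genes were called downward as well (median -0.86, adjusted p = 1.05e-07, but adjusted p = 0.402 with an estimated correlation), with 1 of 91 lower and 1 higher (2 and 1 adjusted over the list alone). In F52 glutathione S-transferases rose in 5 of 70 genes (11 adjusted over the list alone; adjusted p = 3.01e-10, but adjusted p = 0.0782 with an estimated correlation). In I6 and N31 at normal temperature ribosomal proteins were called below WT (medians -0.50 and -0.44, adjusted p = 1.09e-13 and 2.49e-04, but adjusted p = 0.956 and 0.916 with an estimated correlation), with 4 of 778 genes lower and 10 higher in N31 (3 and 8 adjusted over the list alone). In I6 limma called 0 of them, also when adjusted over the list alone.

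Other splits of the arrays showed which counts exceed those of other labellings of the arrays. For the averaged temperature effect 1 of 100 splits, the real one, gave as many as 5177 probes, and the highest other split gave 309, so chance was excluded for the probe count. That other split reversed the temperatures of I6, N31 and WT. Its 10 lists were reached by 27 of 100 splits (highest other 17), so chance was not excluded for the number of lists, whereas the 5 lists with an estimated correlation were reached by 1 of 100 (highest other 2). For the Irp9 lines 1 of 100 splits gave 4357 probes. The highest other gave 1510, from a split that put 3 arrays of F10 and 1 of WT on the WT side. The 10 lists of this comparison were reached by 30 of 100 (highest other 17), so chance was not excluded for the number of lists. For plastidic against cytosolic Irp9 1 of 100 splits gave 3570 probes, the highest other 3037, which kept 3 of the 4 arrays of I6 together. The 14 lists of that comparison were reached by 13 of 100 (highest other 17), with the same reading for lists. The splits of these 2 comparisons moved single arrays between lines and ignored slide and scan. They exclude a random labelling of arrays for the 2 probe counts. Chance differences between lines are not excluded, as there are too few lines to shuffle. For the NahG line, in a fit of 8 arrays alone with temperature as a covariate in place of group means, 2 of 35 splits gave as many as the real 20 probes. The other one, with 405, was the split by temperature, a structure of the samples, and it had to be fitted without temperature as a covariate. Whether chance can be excluded for the probes turns on this split, fitted in another form, and is left open; every other split gave 2 or fewer. Its 4 lists were reached by 21 of 35 (highest other 14), so chance was not excluded for the number of lists. The slide-blocked fit of all arrays called 792 probes.

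The arrays of F10 all came from the third scan, and 3764 probes were called between F10 and WT at normal temperature with a signed median of 1.67. A difference between scans as the whole cause was argued against, since the same probes moved by a signed median of 0.295 between scans within WT at high temperature and by -0.11 within N31 at normal temperature. The third-scan arrays of these 2 pairs stood on slides 5 and 4. Slide 3 held F10 alone (replicate 1 at each temperature), so these values do not test an effect of that slide. With slide as a block 175 probes were called, 153 of them in common. Within the third scan F10 differed from WT at high temperature by a signed median of 0.77, with the same sign for 77.8% of the probes, though 1 WT array stood there. Plastidic Irp9 stays open as a cause: F52, the other plastidic line, differed from I6 by a signed median of 0.386 over these probes, with the same sign for 83.3%, which lay between the bounds set for it. Scan, line and insertion site remain together in F10, as does slide 3 for its replicate 1. A part of its count may therefore be due to scan, to slide or to the line itself.

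Probes called in the NahG line were followed in the comparison of plastidic with cytosolic Irp9, under the hypothesis that the lines form 1 graded response to their capacity for salicylic acid. Medians were 0.0645 for probes lower in the NahG line and 0.0058 for probes higher in it, with members going both ways (53.9% of the lower set rose, 49.4% of the higher set fell). Within slides 1 and 2, which hold F52 and I6 but not F10, they were -0.0557 and -0.0466 for the lower set and 0.271 and 0.0742 for the higher set. The gap between the sets was 0.0587 pooled, -0.326 within slide 1 and -0.121 within slide 2. At normal temperature the graded response was argued against for F52 and I6, as the higher set had medians of 0.459 and 0.263 within the 2 slides. At high temperature these were 0.0664 and -0.107, which leaves it open there. Against I6 the gap was 0.342 for F10 and -0.24 for F52, so the plastidic lines moved apart and the pooled medians near 0 decide nothing for both together. Between slides 1 and 2 the gap moved by -0.436 to -0.0897 within a line and temperature, and F10 stands on other slides than I6. The part of F10 and a difference between slides therefore cannot be told apart here. A bias that follows signal intensity was argued against, as the median of the lower set lay above the -0.124 to -0.0628 of 1000 sets matched on mean signal; that of the higher set also lay above its matched sets (-0.07 to -0.0218), so both were shifted the same way. Of the 786 lower probes, 202 were called higher in the plastidic lines against 44.9 by chance, but of the 1383 higher probes only 48 were called lower against 63.5, so the graded response lacks its counterpart there.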
